A study of Homo sapiens with 2 samples.

How the data were processed

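Small RNA of MCF-7 cells with stably integrated hGH or MUT hGH plasmids was profiled with 1 one-colour miRNA array per group. Per the labels' protocols, the cells were grown in medium with 10% serum and held for 24 h without serum, RNA was isolated with TRIzol and a mirVana kit and labelled with Cy3, and the slides were read on a GenePix scanner. Per the file headers, the deposited scanner files give for each spot the intensity (spot volume in relative fluorescence units), the local background intensity, the background-subtracted volume and the percent of replaced pixels. The subtracted volume equalled volume minus background, set to 0 where negative, in all 3072 spots of each array (tolerance 0.01 units). The quantification program and its settings are not given in the sources used here. The deposited value table holds a ratio: tested against the scanner files, for 1150 of the 1314 rows with a value the authors' value equalled the mean subtracted volume of the 2 spots of its own probe divided by the median of the positive control spots of the array (541926 units for MUT hGH and 980342 for hGH), with column medians of 0.018 and 0.015. The other rows were 154 of star forms, 6 of candidate miRNAs and 4 of miR-142-5p and miR-509-5p. Spots at 0 entered those means as 170 (left) or 100 (right) on the MUT hGH array and as 70 (right) on the hGH array. The direction of the table is not in doubt, since each column matched its own array, and no centring was found. Many of its star forms carry the value of another probe, so it served only as an alternative.

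Each array held 1406 human miRNA spots, 786 spots of candidate miRNAs of the array's maker, 652 blanks, 152 mismatch, shuffled or reversed controls, 48 further controls and 24 positive controls. All 703 human probes were tandem repeats of an antisense unit of 17 to 27 bases. For 5 names there were 2 probes of different sequence, and their spots were averaged. miRNA names are those of the files, which can be old. No genome build is named, so no coordinates are given, and the GRCh38.p14 gene table was used only for names and neighbours.

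Volume and local background were corrected with the normexp model of limma 3.58.1 (R 4.3.3) with an offset of 50 over all spots. Control spots were then left out, the arrays were quantile normalized over the other spots, values were taken to log2, and the spots of a miRNA were averaged. The files used give no background SD and no spot flags, so a spot counted as above background when its net volume exceeded the median of the 652 blank spots by 2 robust SDs (2529 units for MUT hGH and 2450 for hGH). Above these limits lay 34 and 32 of the blanks. A miRNA was above background on an array when more than 50% of its spots were. A difference is hGH minus MUT hGH, and a miRNA was called when it reached 1 on the log2 scale (2-fold). For a miRNA above background on a single array a bound was given, or the measured fold where the dimmer mean exceeded the lowest signal above background on its array. The normexp fit placed the background mean at -8692 and -8267 units, below the blanks, which adds a pedestal and shrinks folds. Tested on simulated data for the hGH against MUT hGH comparison (698 miRNA names), a true log2 difference of 2 came back as a median of 1.04 with 11 of 21 miRNAs called, and as 1.85 with 18 of 21 called after background subtraction. A true difference of 1 was called for 2 of 19 and 6 of 19, and unchanged miRNAs for 0 of 150 and 6 of 150. A true difference of -1 was called for 4 of 15 and 7 of 15, and one of -2 for 1 of 7 and 6 of 7. Both simulated arrays were drawn from the MUT hGH array with independent spot noise, and 200 names were changed in the simulated hGH array. Negative net volumes of probe spots were set to 0 before the draw. The normexp fit of the simulated arrays was not recorded, so the shrinkage on the real arrays may differ. Differences between slides are left out, so the calls among unchanged miRNAs reflect spot noise only. The number of arrays limits the precision: with 1 array per group there was no test, and the SD over spots is technical.

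Apart from the detection limit, the rules for calling, the 20 lists and the rule for named miRNAs were fixed before the data were examined. The planned detection limit, 2 background SDs above the local background, was replaced by the limit from the blanks because no background SD was given. Named were up to 12 miRNAs in each direction with at least a 2-fold difference and no overlap of spots, the 4 largest bounds in each direction, all members of the miR-183 cluster, and the members of each other list with the largest and smallest differences, up to 4. A list's median was ranked among 10000 random lists of the same size matched on mean signal, as a description of these arrays. Alternatives were background subtraction with a floor of 16, an offset of 16, no background correction, other or no normalization between arrays, other detection filters, left or right spots left out, the median over spots and the deposited table (15 planned). A further 6 were added after seeing the data: scaling to the first positive control, with and without background subtraction, scaling to candidate probes, background subtraction with centring on the miRNAs above background on both arrays, a detection limit at the 95th percentile of the mismatch spots, and leaving out spots with over 10% replaced pixels. The planned use of foreground means and of spots with a negative flag was not run, as the files used have no such columns.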

Results

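MicroRNAs were profiled in MCF-7 cells, an established human breast cancer line of luminal type that expresses the oestrogen receptor, carrying either of a pair of stably integrated plasmids. The hGH cells carried a plasmid with the wild-type human growth hormone gene, and the MUT hGH cells carried the same gene with its start codon disabled (ATG changed to TTG), so that no hormone is translated from it. Both were kept for 24 h in serum-free medium before RNA was prepared, and the small RNA, labelled with Cy3, was hybridised to a one-colour miRNA array. The series contrasts the pair to ask which miRNAs differ in cells that make their own growth hormone. The files used here hold 1 array per group, each labelled as standing for 2 replicates without saying what these are, and each probe was read from 2 spots per array. No test, standard error or p-value can be given for a difference between the groups, and the errors below are SDs over the 2 spots of a probe on an array. Each array carried 3072 spots, of which 1406 were for human miRNAs (703 probes with 698 names). Net signal over all spots was 102336000 fluorescence units on the MUT hGH array and 124500000 on the hGH array. Human miRNA probes took 6.34% of it on the MUT hGH array and 8.52% on the hGH array, and 44.3% and 50.6% of their spots, respectively, exceeded the limit set by the blank spots. The growth hormone transcript has no probe among these miRNAs, so the array does not check the labels of the cells.

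In the hGH cells, 5 miRNAs were at least 2-fold higher than in the MUT hGH cells, and 0 were at least 2-fold lower. The largest difference was that of miR-342-3p, a miRNA well expressed in luminal breast cancer lines, whose normalized log2 signal was 14.63 ± 0.04 with MUT hGH and 16.86 ± 0.18 with hGH (SD over 2 spots), 4.71-fold higher. miR-16, which represses BCL2 and several cyclins, stood at 15.15 ± 0.63 and 17.24 ± 0.19, 4.28-fold higher. let-7c, of the let-7 family that represses RAS and HMGA2, was 2.25-fold higher (15.84 ± 0.39 and 17.01 ± 0.18). miR-106b, a relative of miR-17 that represses the cell cycle inhibitor CDKN1A, was 2.17-fold higher (13.96 ± 0.22 and 15.07 ± 0.02), and miR-30d, of the miR-30 family of epithelial cells, was 2.12-fold higher (14.78 ± 0.03 and 15.86 ± 0.07). The spots of all 5 lay wholly above those of the MUT hGH array. Their probes repeat the antisense units ACGGGTGCGATTTCTGTGTGAGA for miR-342-3p, GCCAATATTTACGTGCTGCTA for miR-16, AACCATACAACCTACTACCTCA for let-7c, ATCTGCACTGTCAGCACTTTA for miR-106b and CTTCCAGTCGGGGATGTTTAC for miR-30d. The nearest other human probe lay 9 edits away for miR-342-3p, 2 for miR-16 (miR-195), 1 for let-7c (let-7a), 4 for miR-106b and 3 for miR-30d (miR-30a), so signal of near relatives can be shared. miR-638 had the largest negative difference, -0.997 on the log2 scale (15.77 ± 0.38 and 14.77 ± 0.02), just short of 2-fold, and is named because of that value.

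The difference has no replicate check, and clone, slide and plasmid cannot be told apart. The calls also depended on the processing: background subtraction in place of the normexp model gave 29 higher and 14 lower miRNAs and moved miR-106b to 3.37-fold and miR-638 to -1.24, scaling to the positive control spots gave 2 higher and 20 lower, and let-7c, miR-106b and miR-30d were under 2-fold in 5, 3 and 6 of 21 alternatives, whereas miR-342-3p and miR-16 stayed at least 2-fold higher in all 21.

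**Figure D1:**
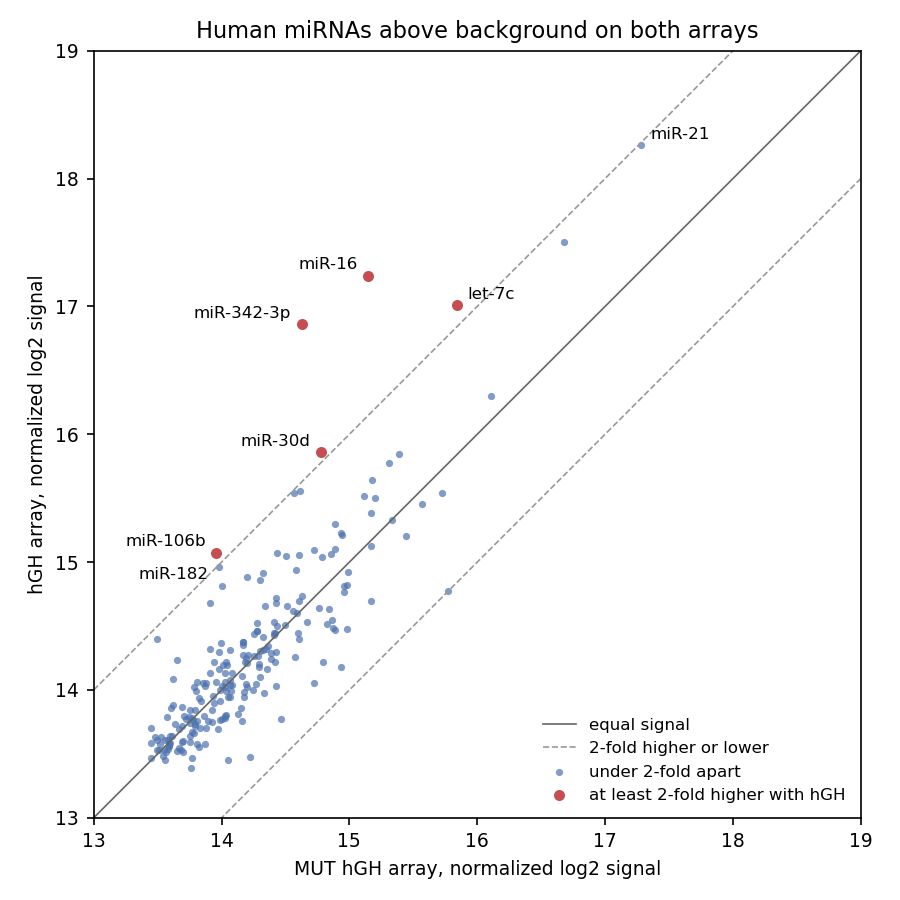
Normalized log2 signal of the 219 human miRNAs above background on both arrays, MUT hGH on the x axis and hGH on the y axis, 1 point per miRNA (mean of its spots). The solid line marks equal signal and the dashed lines 2-fold; the 5 red points above the upper dashed line are miR-342-3p, miR-16, let-7c, miR-106b and miR-30d, and miR-182 and miR-21 lie just under it.

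Of the 698 named miRNAs, 309 were above the limit set by the blank spots on at least 1 array: 219 on both, 71 on the hGH array only and 19 on the MUT hGH array only. The mismatch, shuffled and reversed control spots passed that limit about as often as the human miRNA spots (48.0% on the MUT hGH array and 53.9% on the hGH array), and a limit drawn from these controls left 46 miRNAs in place of 309. Across the 219 miRNAs on both, signals of the arrays correlated with a Pearson r of 0.86 and a Spearman rho of 0.85 (miRNAs are not independent replicates). The median difference was 0.01 on the log2 scale, with quartiles of -0.13 and 0.19, and 192 miRNAs (87.7%) lay within 0.5, on a scale on which a simulated 2-fold increase came back as a median of 0.47. The SD of the differences was 0.39 (0.61 with background subtracted), against 0.21 (0.39) for a contrast of left and right spots that holds no difference between groups. Spots of the arrays did not overlap for 82 of the 219 miRNAs (37.4%), where chance alone gives 33.3%.

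Among miRNAs above background on the hGH array only, miR-34a, a target of p53, was at least 1.71-fold higher, miR-487a at least 1.48-fold and miR-296-5p at least 1.45-fold, each bound being set against the lowest signal above background on the dimmer array. For miR-541 the dimmer mean exceeded that lowest signal, and the value is its measured fold, 1.52-fold higher, not a bound. Spots of miR-487a and miR-296-5p overlapped between the arrays. Their MUT hGH spots had SDs of 3.25 and 3.28 and mean net volumes of -22680 and -21392 units, so their bounds do not hold spot by spot. Among those above background on the MUT hGH array only, miR-517c was at least 1.73-fold lower with hGH and miR-665 at least 1.25-fold, while miR-374a and miR-374b had measured folds of 1.33 and 1.31. With background subtracted all 8 passed 2-fold, with log2 values of 1.69 to 2.11 for the higher and -1.27 to -1.93 for the lower. Single spots decided several of them: without the right spots miR-541 came to 0.015, miR-487a to -0.15, miR-296-5p to -0.40 and miR-374a to 0.05, and without the left spots miR-517c came to -0.11. Without background correction miR-541 came to 0.05, miR-374a to -0.05 and miR-374b to -0.04. With positive control scaling miR-34a came to 0.07, but to 1.70 with background also subtracted. In the deposited table its measured difference was 1.76.

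The miR-183 cluster (miR-96, miR-182 and miR-183), transcribed together and with neighbouring genes in the GRCh38.p14 annotation, was listed because the study's paper is known to concern it, so its values are not independent evidence of a direction. Of its 3 measured members 2 were above background on both arrays, both higher with hGH, and 0 reached 2-fold. miR-182 was 1.98-fold higher (13.98 ± 0.15 and 14.97 ± 0.14, spots not overlapping), and miR-183 was 1.19-fold higher with overlapping spots (14.06 ± 0.34 and 14.32 ± 0.13). miR-183 differed by 0.0099 without the left spots and by -0.33 with positive control scaling, and miR-182 by 0.43 with that scaling and by a bound of 0.24 with the mismatch limit. miR-96 was not above background on either array and has no value in the deposited table. Its other arm, miR-96*, named after its value was seen, differed by -0.37 (13.76 ± 0.44 and 13.39 ± 0.0041) and by -1.18 with background subtracted, and miR-183* differed by 0.21. The median difference of the pair was 0.62, at the 98.6th percentile of 10000 random lists of the same size and signal. With background subtraction miR-182 passed 2-fold at 2.94-fold and the median came to 1.02. Scaling to the first positive control left a median of 0.054, over a median of all miRNAs that this scaling sets at -0.63. With both combined the median of the pair was 0.66, over -0.34 for all miRNAs. In the authors' deposited table the log2 difference was 1.19 for miR-182 and 0.07 for miR-183.

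**Figure D2:**
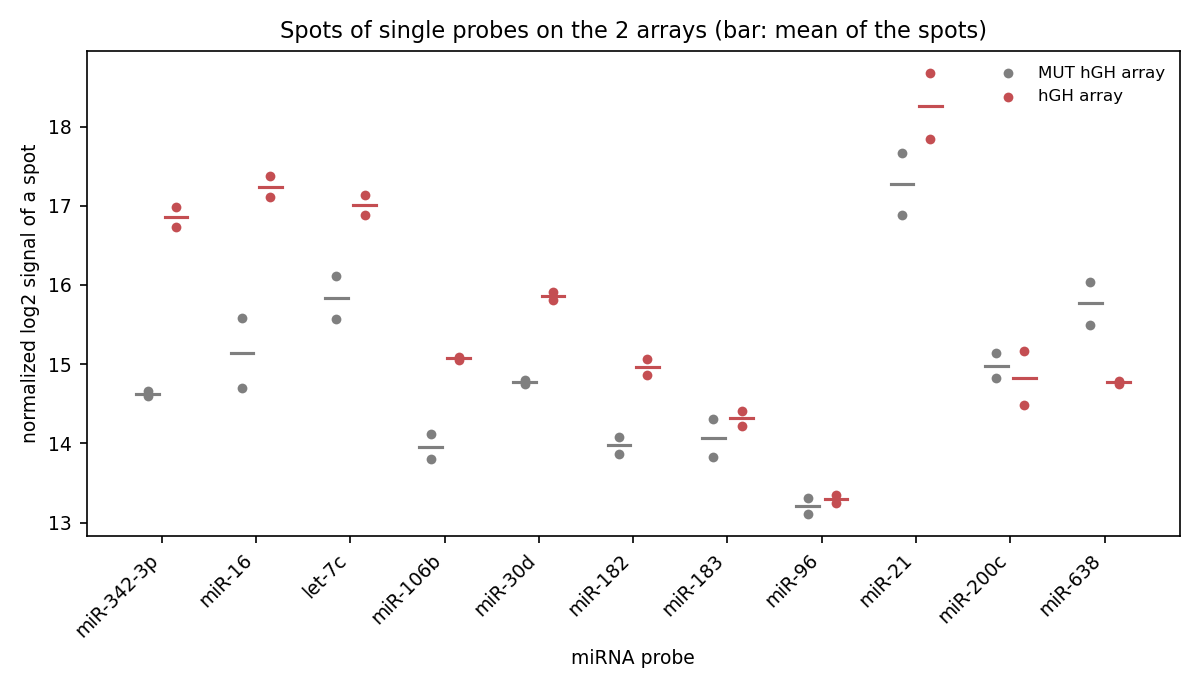
Normalized log2 signal of each spot (points) and the mean of the 2 spots (bars) for 11 probes, MUT hGH array in grey and hGH array in red. The spots of miR-342-3p, miR-16, let-7c, miR-106b, miR-30d, miR-182 and miR-21 on the hGH array lie above those on the MUT hGH array, those of miR-638 lie below, and those of miR-183, miR-96 and miR-200c overlap.

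Other families were described in the same way, each median being a log2 difference (hGH minus MUT hGH) over the members above background on both arrays. Of the list members named, with those of the miR-183 cluster included, 48 were above background on both arrays. The sign of the difference turned for 17 of these 48 when the left or the right spots were left out. It turned for 13 with positive control scaling and for 14 without normalization, which move the median of all miRNAs to -0.63 and 0.22. In the deposited table that median was -0.32, so its values below also hold such a shift. Of the 55 list members on both arrays under 2-fold, 16 passed it in at least 1 alternative. In the miR-15/16 family, which acts on BCL2 and the cell cycle, 4 of 6 measured members were above background on both arrays, all 4 higher with hGH and 1 by at least 2-fold. Their differences were 2.10 for miR-16, 0.81 for miR-15b (1.30 with background subtracted), 0.07 for miR-15a and 0.02 for miR-195, with a median of 0.44 at the 96.4th percentile of random lists, below 0 in 1 of 21 alternatives (-0.12 with positive control scaling). In the let-7 family, 8 of 9 members were above background on both arrays, 6 higher and 2 lower, with a median of 0.33 (75.1st percentile, below 0 in 3 of 21 alternatives). Beside let-7c, let-7d differed by 0.83 (0.034 with quantiles over human probes, 1.18 with cyclic loess and 1.30 without normalization), let-7b by -0.19 and miR-98 by -0.31. All 9 let-7 probes lie within 3 edits of another human probe.

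In the miR-17 clusters, which are driven by MYC and E2F and promote proliferation, 8 of 13 members were above background on both arrays, 4 higher and 4 lower. The median of -0.0028 and the mean of 0.08 differed in sign, and miR-106b was the 1 member past 2-fold. miR-18b differed by -0.32 and miR-20b by -0.50. miR-20a, above background with hGH only, was at least 1.19-fold higher (a log2 bound of 1.003 with background subtracted). In the authors' deposited table the measured differences were -1.05 for miR-20b, 1.56 for miR-20a and 1.27 for miR-25, which was also on the hGH array only. The miR-30 family likewise had a median of -0.08 (23.4th percentile, above 0 in 3 of 21 alternatives) and a mean of 0.24: miR-30a differed by -0.08 and miR-30e by -0.29 beside 1.08 for miR-30d, and miR-30b was above background with hGH only, with no fold above 1. In the miR-34 family, 0 of 3 members were above background on both arrays, and miR-34b, on the hGH array only, had a measured fold of 1.11 with overlapping spots.

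The miR-200 family, which keeps cells epithelial by repressing ZEB1 and ZEB2, was above background on both arrays for all 5 members, 2 higher and 3 lower, with 0 at 2-fold. In the authors' deposited table miR-429 passed it at -1.248, as it did with positive control scaling (-1.06). Values ran from 0.16 for miR-200a and 0.03 for miR-200b to -0.16 for miR-200c and -0.40 for miR-429 (-0.83 with background subtracted), with a median of -0.02 (30.1st percentile, above 0 in 4 of 20 alternatives). In the miR-29 family miR-29a differed by 0.37, miR-29c by 0.21 and miR-29b by -0.01 (median 0.21, 94.8th percentile, below 0 in 1 of 20 alternatives). In the miR-23/27/24 clusters miR-23a differed by 0.27, miR-23b by 0.19, miR-24 by 0.0063 and miR-27b by -0.12 (median 0.10, 84.6th percentile, below 0 in 4 of 20 alternatives).

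Among miRNAs that promote invasion in breast cancer, 3 of 6 were above background on both arrays and 0 reached 2-fold. miR-21 was 1.98-fold higher with hGH (17.28 ± 0.56 and 18.26 ± 0.59), whereas miR-155 differed by -0.48 and miR-520c-3p by -0.32 (-1.01 and -1.12 in the authors' deposited table), and miR-373, on the hGH array only, was at least 1.10-fold higher. The difference of miR-21 was 0.15 in place of 0.99 with quantiles over human probes and 0.46 with positive control scaling, and it passed 2-fold at 1.31 without normalization. The median was -0.32 (1.1st percentile, above 0 in 3 of 21 alternatives) and the mean 0.06, of opposite sign. Of 7 measured miRNAs that restrain invasion, 4 were above background on both arrays: miR-125a-5p differed by 0.41, miR-146b-5p by 0.0055, miR-31 by -0.12 and miR-146a by -0.39, or -1.05 without the left and 0.33 without the right spots (median -0.06, 29.6th percentile, above 0 in 3 of 20 alternatives). Among miRNAs that act on or respond to the oestrogen receptor, 2 of 6 were above background on both arrays, miR-193b at 0.69 (1.10 with background subtracted) and miR-18a at -0.01 (median 0.34, 85.1st percentile, below 0 in 2 of 20 alternatives), and miR-221, miR-222, miR-206 and miR-22 were not above background on either array. Neither was miR-210, a target of the hypoxia factor HIF. Of 10 miRNAs abundant in luminal MCF-7 cells, 8 were above background on both arrays, 5 higher and 3 lower, from miR-342-3p at 2.24 and miR-21 at 0.99 to miR-107 at -0.20 and miR-103 at -0.23 (median 0.17, 49.1st percentile, below 0 in 3 of 21 alternatives).

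Markers of other cell types were mostly not above background. This does not check the identity of the cells, since 389 of all 698 human miRNAs were above background on neither array. In the main analysis 0 of the markers reached 2-fold. With background subtracted miR-144 and the miR-128 probe did, as did miR-372 (-1.02) with positive control scaling, and miR-137 (-1.04) and miR-367 (-1.01) with both combined. In the authors' deposited table the values were -1.26 for miR-372 and -1.08 for miR-137. The miR-128 probe, not above background with MUT hGH, had a measured difference of 2.65 there. Of 7 blood miRNAs, 5 were not above background on either array. miR-144 differed by -0.75 with overlapping spots, by 0.0068 with the right spots left out, by -1.44 with the left spots left out and by -1.60 with background subtracted. miR-142-5p, with 2 probes of different sequence, was above background with MUT hGH only but gave no bound, as its mean was not lower with hGH. Its measured difference was 0.08, or -0.50 with background subtracted. Of 6 stromal miRNAs only miR-214 was above background on both arrays (-0.08), and of 5 muscle miRNAs only miR-1 (-0.04). Among 7 neural entries, miR-138 differed by 0.11, miR-9* by -0.13 and miR-137 by -0.28 (median -0.13, 21.1st percentile, above 0 in 1 of 20 alternatives), and the probe shared by miR-128a and miR-128b, on the hGH array only, was at least 1.23-fold higher (a log2 bound of 1.13 with background subtracted). The liver marker miR-122 was not above background. Of 8 pluripotency miRNAs, 3 were above background on both arrays, with differences of -0.0087 for miR-302b, -0.29 for miR-372 and -0.35 for miR-367. Their median was -0.29 (1.4th percentile, below 0 in all 20 alternatives that gave it). The mismatch limit gave no median, as it left none of them above background on both arrays. A shuffled control of miR-200c had net signals of 17870 (MUT hGH) and 24582 (hGH), above those of all 3 miRNAs.

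**Figure D3:**
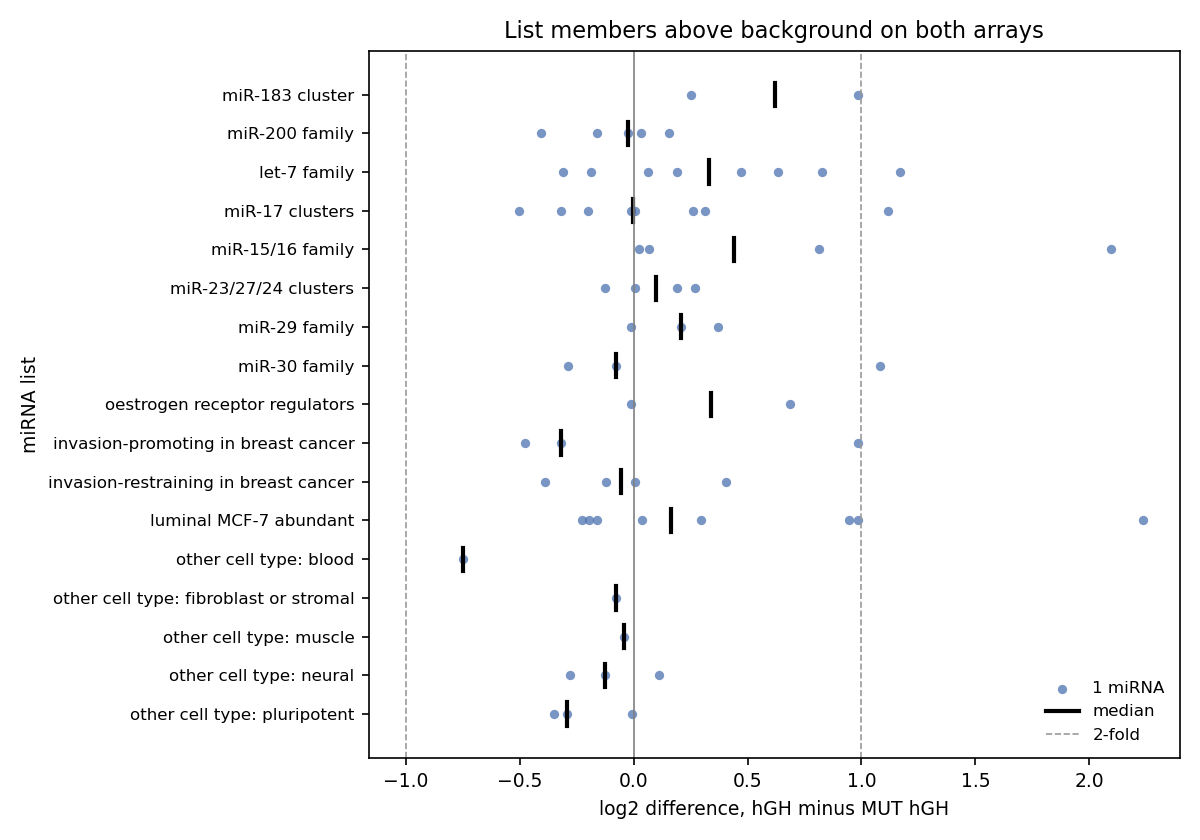
Log2 difference (hGH minus MUT hGH, x axis) of each list member above background on both arrays (points) and the list median (black bars), for the 17 of 20 lists with such a member. The dashed lines mark 2-fold; 4 miRNAs pass the right line within their lists (miR-16, let-7c, miR-106b and miR-30d) beside miR-342-3p among the luminal miRNAs, and 0 pass the left line.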

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

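The tests in this part were chosen after the results were seen. Signal appeared in spots that the comparisons above do not use. The candidate miRNA probes, sequences proposed by the array's maker, were above background on both arrays for 274 of 392 names. Of the mismatch, shuffled and reversed control spots, 73 of 152 on the MUT hGH array and 82 of 152 on the hGH array exceeded the limit set by the blanks.

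For the 5 miRNAs at least 2-fold higher with hGH, a scale for noise came from contrasts of left and right spots, which hold spot noise and blemishes but no difference between groups and reached at most 0.81 among the 219 miRNAs (1.69 with background subtracted). miR-342-3p and miR-16 exceeded that by at least 1.29 (0.71), which argues against noise. Their smallest difference over the other scalings was 1.40, so they stayed at least 2-fold higher under each scaling tried. This pair was set apart after the results were seen, so these values cannot test the scaling between arrays. let-7c, miR-106b and miR-30d exceeded the largest noise contrast by at least 0.27. Not all did with background subtracted (lowest margin -0.40), so noise stays open for these 3. Over the other scalings the smallest differences of these 3 were 0.24 for let-7c, 0.56 for miR-106b and 0.62 for miR-30d. The values for miR-106b and miR-30d came with positive control scaling, which sets the median of all miRNAs at -0.63. With quantiles over human probes they were 1.03 and 0.86. Scaling may thus also carry these 3 past 2-fold, let-7c most of all. Among the scalings, miR-106b was under 2-fold only with that to the positive control. An effect of hGH itself and a difference between clones or slides cannot be told apart with 1 array per group.

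The positive control spots were brighter on the hGH array by 1.81, 1.06 and 1.54 times for the 3 control sequences, while the miRNAs above background on both arrays had a median net log2 ratio of 0.50. A common labelling or hybridisation factor would shift them alike, but the log2 shifts of the 3 controls spanned 0.77, which argues against it. Against the miRNA median the first control shifted by 0.36 on the log2 scale, the second by -0.42 and the third by 0.12, so they point both ways. Whether they reflect a different amount of small RNA in the labelled samples stays open, because what the controls are made of is not given. No biological explanation was tested.

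In the authors' deposited table, star forms (the minor arm of a hairpin) often carry the value of another probe. Of the 105 star probes with a value, 74 had an unstarred probe with a value, and all 74 carried exactly that value (tolerance 0.01%), 28 their own and 3 that of another probe whose name starts alike. A lookup by name in which the star stands for any characters is a candidate explanation that this count of 74 meets. Equal levels of both arms are argued against, since 51 of the star probes with the unstarred value were themselves above background on neither array. For the star probes with the unstarred value and signal of their own, the table value on the hGH array was a median of 10.0 times their own.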

How the results depend on the processing

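Of the alternatives, 6 were chosen after seeing the data: scaling to positive controls or candidate probes, background subtraction combined with another scaling, the limit from mismatch probes and the filter on replaced pixels. The correlation of the arrays was 0.82 to 0.86 (lowest without left spots), except 0.73 with the mismatch limit. The mismatch limit left 46 miRNAs above background in place of 309. Counts at least 2-fold higher and lower with hGH (5 and 0) became 29 and 14 with background subtracted. With background subtracted and median centring they were 23 and 20, and with background subtracted and positive control scaling 11 and 34. Positive control scaling alone gave 2 and 20, and the deposited table gave 15 and 27. The counts of the deposited table took measured differences in place of bounds and include star forms that carry the value of another probe. The count of higher miRNAs was 3 without background correction, 14 without normalization, 3 with quantiles over human probes and 10 with scaling to candidate probes. The count of lower miRNAs was 1 with 75th percentile scaling, with quantiles over human probes and with replaced-pixel spots left out, 3 without left spots and 5 without right spots. The miR-183 cluster median (0.62) was 1.02 with background subtracted, 0.91 without normalization and 0.92 with background subtracted and median centring. It was 0.054 with positive control scaling alone and 0.66 with background also subtracted, and above 0 in all 20 alternatives that gave it. Positive control scaling moved the median of all miRNAs above background on both arrays to -0.63, or to -0.34 with background also subtracted. In the deposited table, whose values are ratios to the positive controls, that median was -0.32. Without normalization it was 0.22. The other causes were not tested. With background subtracted, the 2 contrasts of left and right spots themselves gave 6 higher and 1 lower, and 4 higher and 5 lower miRNAs, against 15 and 7 among the 219 miRNAs above background on both arrays. Of the 1179 values of named miRNAs under alternatives, 841 stayed within 0.21 of the reported value, as did 243 of 322 list medians. The foreground mean and flag alternatives were not run, the mismatch limit gave no miR-183 cluster median, and the deposited table gave no count of detected miRNAs. No paired analysis, slide block or left-out replicate was possible because each group is 1 array on its own slide.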

Other observations

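The tests in this part were chosen after the results were seen, as were the miRNAs named here. Beside those described above, several miRNAs were under 2-fold and passed it with background subtracted (values in parentheses). Higher with hGH, miR-151-5p and miR-151-3p, the arms of a hairpin in the gene of the focal adhesion kinase PTK2, differed by 0.90 (2.10) and 0.58 (1.29) on the log2 scale. miR-181a differed by 0.98 (1.27), miR-203 of the luminal list, which represses the epithelial stem cell factor TP63, by 0.94 (1.22), miR-454 by 0.77 (1.31) and miR-186* by 0.47 (1.17). Lower with hGH, miR-148a* differed by -0.60 (-1.67), miR-340 by -0.69 (-1.18), miR-923 by -0.75 (-1.17) and miR-216a by -0.30 (-1.004), beside miR-638 and miR-96*. With background subtracted, contrasts of left and right spots reached 1.69 in size, and of these miRNAs only miR-151-5p exceeded that. Without subtraction they reached 0.81, which miR-151-5p, miR-181a, miR-203 and miR-638 exceeded. The subtracted MUT hGH spots had an SD of 1.38 for miR-340.

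Across the 274 candidate miRNA probes above background on both arrays, the arrays correlated with r = 0.95, and among all candidates 18 were at least 2-fold higher and 7 at least 2-fold lower with hGH. The largest difference was 4.51-fold for a candidate at 16.07 ± 0.13 and 18.24 ± 0.52 (SD over 2 spots). These probes took 77.7% of the net signal on the MUT hGH array and 71.5% on the hGH array.

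A mismatch control derived from rat miR-16 had a ratio near that of the human miR-16 probe. Net signal on the hGH array was 6.93 times that on the MUT hGH array for miR-16, and 7.19 times for the mismatch probe 2 edits from the miR-16 unit. The mismatch probe 3 edits away was not above background on the MUT hGH array, and its ratio was at least 3.12 against the limit there. For the shuffled form, 8 edits away, the ratio was 1.81.

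A hypothesis was that both arms of a hairpin differ alike, as a shared change of the hairpin would give. Over the 14 hairpins with both arms above background on both arrays, the differences correlated with a Pearson r of 0.62 and a Spearman rho of 0.74. Of 100000 shuffled pairings, 3.97% gave a Pearson r and 0.38% a Spearman rho as large in size, and without the pairs farthest from the median, miR-342 and miR-144, r was 0.76. This is consistent with a shared change of the hairpin, on 1 array per group and over hairpins that are not replicates. The arms of miR-342 differed by 2.24 (3p) and 0.59 (5p), and those of miR-151 both differed by over 0.5.

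A related hypothesis, that miRNA genes within 10 kb of each other differ alike, was not settled. Of 181 names, 162 (89.5%) matched a gene in the GRCh38.p14 table and gave 64 neighbouring pairs. Their mean absolute gap was 0.33 on the log2 scale, against 0.40 on average for shuffled genes, and 13.6% of 10000 shuffles gave a gap as small. Without pairs whose probes lie within 3 edits, the gap was 0.31 over 55 pairs, and 9.34% of shuffles gave one as small. Single pairs went both ways: beside miR-16 (2.10), which has copies at 2 loci, stood miR-15b at 0.81 and miR-15a at 0.07, and beside miR-106b (1.12) stood miR-93 at 0.0060.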
